A study of Drosophila melanogaster with 8 samples.

How the data were processed

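The measurements were transcript levels in cultured Drosophila melanogaster S2 cells, a macrophage-like embryonic line used here as the S2-6 isolate, 4 days after double-stranded RNA (dsRNA) was given to the cells. There were 8 samples on 8 arrays of 1 colour (Cy3). Of these, 3 had received ade2 dsRNA1, 2 had received ade2 dsRNA2, and 3 had received a non-specific dsRNA with a Chlamydomonas lhcb sequence, here called lhcb dsRNA. Groups and replicate letters were taken from the sample labels. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

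Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 9.1.3.1, which reports each spot's intensity on a linear scale after subtracting background and removing spatial trends within the array. These deposited intensity values can be 0 or negative, and no step between arrays had been applied to them. Each array had 45020 spots, of which 1417 were controls that were left out, and the other 43603 spots covered 32162 probes. The share of spots well above background, as the scanner software marks it, was 64.9% to 67.0% per array. Signals at or below 0 made up 8.99% to 12.4% of spots, and no spot was saturated. The number of arrays limits the precision.

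The authors' deposited table of processed values was an alternative only. Per array, its values equalled the scanner's processed signal divided by a constant of 615 to 838, with values under 0.01 set to 0.01, for 99.8% to 100% of probes within 1%. Its scale is linear and not centred per gene, with medians of 0.0788 to 0.0996 per array, and 25.2% to 29.6% of its values were at the minimum. What the constant stands for is not given in the sources used here, and the table holds levels, not ratios.

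Spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. Each processed signal was divided by its array's 75th percentile, which lay between 2463 and 3123, a floor of 0.00217 was set on the scaled signal (5.35 to 6.78 intensity units), and log2 was taken. The floor was the highest, over the arrays, of the lowest scaled signal among spots well above background, and 0.194% of the tested values were at it. Probes were named through the gene identifiers in the scanner files and a RefSeq gene table (assembly Release 6 plus ISO1 MT), from which no coordinates were used because the files name no genome build. Of the probes, 20712 matched that table, 663 had an identifier it does not list, and 10787 carried only an accession and were analysed apart. A gene was tested if a probe was well above background on every array of at least 1 group, and its probe was the one with the highest mean signal. This left 20543 probes and 10007 genes, 3525 of them with more than 1 passing probe. Of these genes, 9419 were well above background on all 8 arrays. A gene not well above background on any array of a group has only a bound there, given as "at least" a fold. The dim side was the higher of the floor and the measured signal. Such a bound holds only for the floor and the background step used.

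Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group over all 8 arrays, 5 residual degrees of freedom) and adjusted with Benjamini-Hochberg at 0.05 over the genes tested. The contrasts were each ade2 dsRNA against lhcb dsRNA, the mean of both ade2 dsRNAs against lhcb dsRNA, and ade2 dsRNA1 against ade2 dsRNA2. All adjusted p-values of genes are from limma and are two-sided. Standard errors (SE) of log2 fold changes are limma's moderated ones. Gene lists were tested with camera, with a preset correlation of 0.01 between genes, on the mean contrast; camera with an estimated correlation and fry were run beside it. Of 27 lists, 26 had at least 5 tested genes. Each list's median was also set against 10000 random lists of the same size drawn from 20 signal-level bins. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

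The tests, the groups, the gene lists, the alternatives other than 4 and the rule for the genes named were fixed before the data were examined. The rule took all measured genes of purine synthesis. It took the 12 highest and 12 lowest genes changed the same way with both ade2 dsRNAs and well above background on every array. It took the 3 genes per direction with the highest bounds among those above background on all arrays of one side and none of the other. From each list it took up to 4 members with the largest change past the threshold, and from the contrast between the ade2 dsRNAs the 5 highest and 5 lowest genes under the same background rule. It gave 42 genes, and any other gene named was chosen after its values were seen. The 4 alternatives added later included accession-only probes, used the arrays of slide 1 or of slide 2 alone, or left out lhcb dsRNA replicates a and c together. The others changed the scaling, the background correction, the source of the values, the filter, the choice of probe, the variance model, the array weights, the arrays in the fit, the blocks, the tool or the fold threshold, or left out each array in turn.

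The arrays lay on 2 slides of 4, each with all 3 groups: slide 1 held 2 ade2 dsRNA1, 1 ade2 dsRNA2 and 1 lhcb dsRNA array, and slide 2 held 1, 1 and 2. The fit was therefore repeated with the slide as a block and on each slide alone. A slide alone has 4 arrays for 3 groups, some of them of 1 array, so a lack of calls there decides nothing. The steps were tested on simulated data made from these arrays' spread in 10007 genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. For ade2 dsRNA1 against lhcb dsRNA, 67 and 91 of them were recovered; for ade2 dsRNA2, 56 and 88; for the mean of both, 73 and 92; and between the ade2 dsRNAs, 52 and 88. False calls numbered 4 to 6 in these contrasts. Genes called with both ade2 dsRNAs were recovered in 51 and 88 cases, with 0 false calls. The simulated noise was independent and had the same spread on every array. In the data lhcb dsRNA replicates a and c varied more than the other arrays, so these counts may be too favourable.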

Results

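Transcript levels were measured in Drosophila S2-6 cells collected 4 days after dsRNA was added. Double-stranded RNA taken up by these cells triggers RNA interference, which destroys transcripts that match it. The target, ade2 (CG9127, named Pfas in current annotation), encodes phosphoribosylformylglycinamidine synthase, an enzyme of de novo purine synthesis. It was targeted with a pair of dsRNAs that do not overlap in sequence, ade2 dsRNA1 (n = 3 arrays) and ade2 dsRNA2 (n = 2). The control cells had received lhcb dsRNA (n = 3). Signals of the 10007 tested genes correlated between arrays, across genes, at 0.992 to 0.998. On all arrays together, the first principal component held 37.6% of the variance and set lhcb dsRNA replicate c apart from the other 7 arrays.

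The first question was whether each dsRNA lowered its target. The ade2 transcript had a mean processed signal of 7749 ± 1441 intensity units (SD, n = 3) with lhcb dsRNA. It was at 1397 ± 39.2 (SD, n = 3) with ade2 dsRNA1 and at 1531 ± 99.6 (SD, n = 2) with ade2 dsRNA2. After scaling, ade2 fell 5.73-fold with dsRNA1 (log2 fold change -2.52, SE 0.06, limma adjusted p = 6.93e-06). It fell 4.65-fold with dsRNA2 (log2 fold change -2.22, SE 0.07, adjusted p = 3.64e-05). All 5 ade2 dsRNA arrays lay below all 3 lhcb dsRNA arrays. The difference in ade2 between the dsRNAs, -0.30 on the log2 scale, did not pass the threshold (adjusted p = 0.218). For the mean of both dsRNAs the log2 fold change was -2.37, the same value with the slide as a block, with -2.41 within slide 1 and -2.34 within slide 2. The transcript was read by 1 probe, printed 2 times per array.

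**Figure D1:**
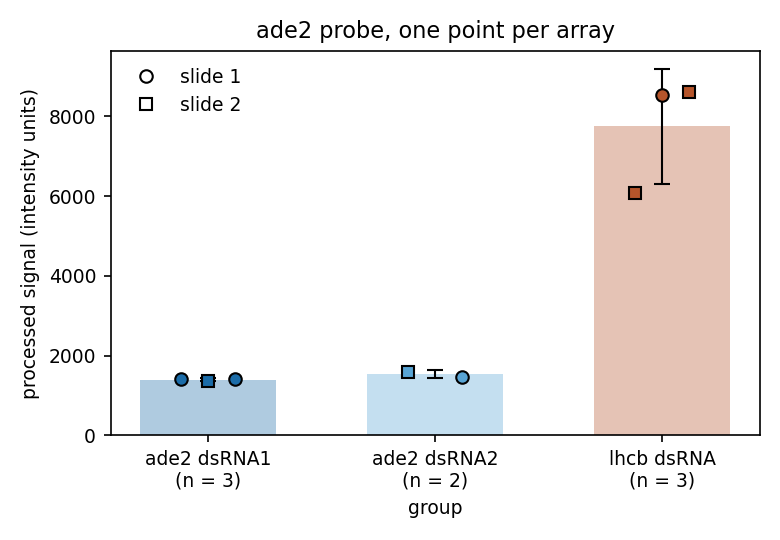
Processed signal of ade2 (linear intensity units) in cells given ade2 dsRNA1, ade2 dsRNA2 or lhcb dsRNA; bars are group means, error bars SD, and points single arrays (circles slide 1, squares slide 2). The ade2 dsRNA arrays lie between 1352 and 1601, all below the lhcb dsRNA arrays at 6086 to 8613.

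With ade2 dsRNA1 against lhcb dsRNA, the highest genes were the odorant receptor gene Or85b, up 7.28-fold (log2 2.86, SE 0.28), and CG11436, up 5.60-fold (log2 2.48, SE 0.06). Fkbp59, an FK506-binding immunophilin, rose 2.63-fold (log2 1.39, SE 0.07), and HtrA2, a mitochondrial serine protease, rose 2.20-fold (log2 1.13, SE 0.09). Apart from ade2, the lowest gene measured on all arrays among those named by the fixed rule was sesB, the mitochondrial ADP/ATP translocase, which fell 3.93-fold (log2 -1.97, SE 0.12). The nucleotidase gene veil fell 2.24-fold (log2 -1.16, SE 0.10), and the proteasome subunit gene Prosbeta7 fell 1.89-fold (log2 -0.92, SE 0.06). CG6660 and CG3649 were well above background on all lhcb dsRNA arrays and on no ade2 dsRNA1 array. With the floor used, that puts them at least 19.2-fold and at least 8.39-fold lower. Members of fixed lists that rose with dsRNA1 included NimC1, a phagocytosis receptor (log2 0.78), Ldh, lactate dehydrogenase (0.60), PGRP-SD, of peptidoglycan recognition (0.58), and Hsp22, a mitochondrial small heat shock protein (0.55).

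In the test over all genes, 189 passed the threshold with ade2 dsRNA1, 150 higher and 39 lower, and 13 of them changed at least 2-fold, 7 up and 6 down. An unadjusted p under 0.05 was reached by 1815 genes. Blocked by slide, 126 passed, 98 higher and 28 lower, of which 107 were among the 189, and of the 30 genes named here that passed, 25 still did. All 30 had the same sign on both slides. On 1 slide alone limma called 0 genes, with 1775 at an unadjusted p under 0.05 on slide 1 and 254 on slide 2. The excess of higher genes depended on the scaling: median centring, under which the median of all genes was -0.14, gave 26 higher and 20 lower, and the authors' values gave 33 and 19. Leaving out any 1 array other than lhcb dsRNA replicate a or c left 66 to 90 genes.

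With ade2 dsRNA2 against lhcb dsRNA, CG11436 rose 5.22-fold (log2 2.38, SE 0.07), Fkbp59 2.69-fold (1.43, SE 0.07), HtrA2 2.37-fold (1.24, SE 0.10) and CG13796 2.16-fold (1.11, SE 0.13). CG18493 rose 2.07-fold (1.05, SE 0.14), and Gdh, glutamate dehydrogenase, rose 1.69-fold (0.76, SE 0.08). Signals of CG13796 and CG18493 were low with lhcb dsRNA, at a scaled log2 of -7.67 and -6.03, with the floor at -8.85. Arc42 fell 2.57-fold (log2 -1.36, SE 0.10), and CG3168 fell 1.48-fold (-0.57, SE 0.07). A further probe described as CG3168, named only by an accession, read -0.002 with dsRNA2 and 0.24 with dsRNA1. CG6660 and CG3649 were again above background on no ade2 dsRNA2 array, at least 24.0-fold and at least 8.39-fold lower with the floor used. On the log2 scale sesB was at 0.02, veil at -0.06 and Or85b at -0.28 with this dsRNA, none of them past the threshold.

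In all, 43 genes passed the threshold with ade2 dsRNA2, 33 higher and 10 lower, and 11 changed at least 2-fold, 6 up and 5 down. An unadjusted p under 0.05 was reached by 1493 genes. Of the 18 named genes that passed, all had the same sign on both slides. In the fit blocked by slide 18 genes passed, 16 of them among the 43, and 10 of the 18 named genes passed. Within a single slide limma called 0, with 1618 genes at an unadjusted p under 0.05 on slide 1 and 229 on slide 2. Leaving out any 1 array left 8 to 27 genes, the fewest without ade2 dsRNA2 replicate a. Quantile normalization gave 20 higher and 13 lower, median centring 9 and 9, and the authors' values 6 and 6.

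Across both ade2 dsRNAs, 28 genes passed the threshold in each comparison in the same direction, 24 higher and 4 lower. The highest was CG11436, at 2.43 ± 0.05 (log2 mean of both, SE, n = 5 against 3 arrays, adjusted p = 3.61e-06), followed by Fkbp59 at 1.41 ± 0.06 (adjusted p = 0.000139) and HtrA2 at 1.19 ± 0.08 (adjusted p = 0.00367). Among the 24 were also ND-MWFE, a subunit of respiratory complex I (0.89), Gdh (0.69), and Pepck1, phosphoenolpyruvate carboxykinase (0.59). The cytochrome P450 genes Cyp28d1 (0.66), Cyp4p1 (0.58) and Cyp12a4 (0.40) rose. GCS2alpha, the alpha subunit of endoplasmic reticulum glucosidase (0.79), and Plp, a pericentrin-like centrosomal protein (0.61), rose as well. The other named genes that rose with both were CG13796 (0.98), CG18493 (0.91), CG13501 (0.67) and CG6830 (0.65). Over the alternatives the dim genes CG13796 and CG18493 went as low as 0.21 and 0.37. The probes of CG13501 read 0.15 and 0.67. The 4 lower genes were ade2, CG14693 (-0.58), CG6660 and CG3649. The last pair were at least 21.5-fold and at least 8.39-fold lower (adjusted p = 2.08e-05 and 1.61e-06). CG3649 was at the floor on all 5 ade2 dsRNA arrays and CG6660 on 3 of the 5, so these p-values are uncertain. Over the alternatives the log2 fold change ran from -3.20 to -0.49 for CG3649 and from -4.56 to -1.33 for CG6660. Their folds are thus bounds only under the floor and background step used. Pepck1, Cyp4p1 and Cyp12a4 were named after their values were seen.

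Of the 42 named genes, 27 had all ade2 dsRNA arrays on one side of all lhcb dsRNA arrays, which chance gives for 3.57% of genes, though most of the 42 were picked for their change. The named genes kept their sign within each slide in the mean comparison, and blocking by slide moved none by more than 0.07 on the log2 scale. CG11436 was at 2.46 with the block, 2.47 on slide 1 and 2.45 on slide 2. Fkbp59 was at 1.40, 1.40 and 1.39, and HtrA2 at 1.22, 1.29 and 1.16. The shared count was 11 with the slide as a block, 9 of them among the 28, and 5 to 16 with any 1 array left out. On 1 slide alone it was 0 with limma.

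**Figure D2:**
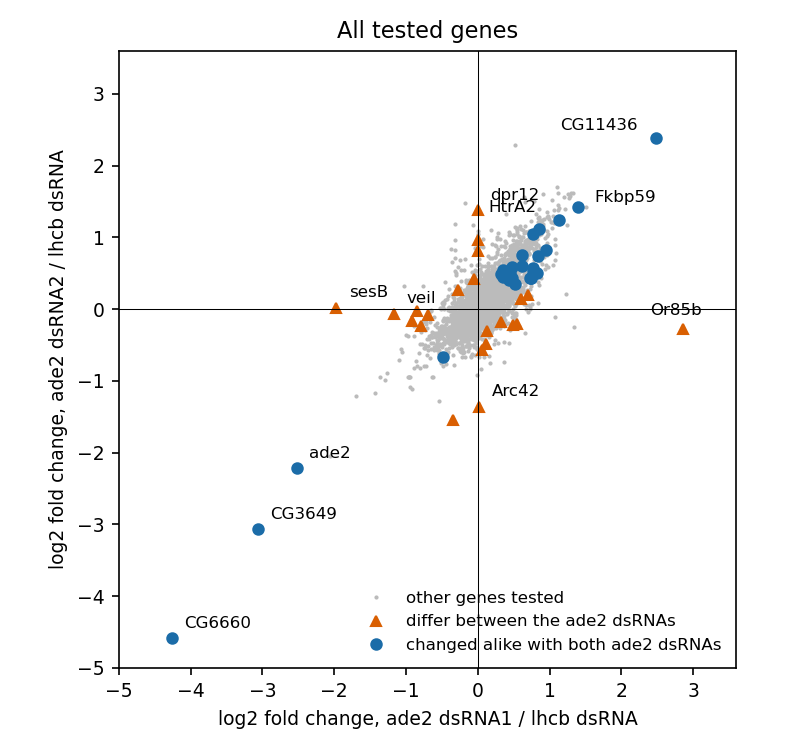
Log2 fold change against lhcb dsRNA with ade2 dsRNA1 (horizontal) and ade2 dsRNA2 (vertical) for the 10007 tested genes; blue circles passed the threshold in the same direction with both, orange triangles differed between the ade2 dsRNAs, and grey points are all other genes. CG11436, at 2.48 and 2.38, and ade2, at -2.52 and -2.22, lie near the diagonal, while sesB, at -1.97 and 0.02, and Arc42, at 0.02 and -1.36, lie near an axis.

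Averaged over both ade2 dsRNAs, 136 genes passed the threshold, 105 higher and 31 lower, and 2040 had an unadjusted p under 0.05. A change with a single dsRNA can pass in this mean. Genes that did so included sesB (-1.97 with dsRNA1, 0.02 with dsRNA2) and Arc42 (0.02 and -1.36). Ir64a, gdrd and dpr12 also passed, with signals at the floor on all dsRNA1 and lhcb dsRNA arrays. Of the 136, 10 changed at least 2-fold. Blocked by slide, 116 passed, 91 of them among the 136, and 25 of the 29 named genes past the threshold still passed, all but pug, RpL13, AlaRS-m and PGRP-SD. On 1 slide alone limma called 0, with 1914 genes at an unadjusted p under 0.05 on slide 1 and 304 on slide 2. Leaving out any 1 array other than lhcb dsRNA replicate a or c left 23 to 75 genes, the fewest without ade2 dsRNA2 replicate a. Quantile normalization gave 67 higher and 35 lower, median centring 14 and 19, and the authors' values 15 and 14.

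The other 9 measured genes of de novo purine synthesis did not pass the threshold singly. Among them Gart was at -0.18 (mean of both, log2), Adsl, adenylosuccinate lyase, at -0.18, Prat, amidophosphoribosyltransferase, at -0.16, Prps, phosphoribosyl pyrophosphate synthetase, at -0.15, and CG11089 at -0.12. IMP dehydrogenase (ras) was at -0.10, Adss at -0.09, GMP synthetase (bur) at -0.09 and Paics at -0.05. Their adjusted p-values were 0.145 to 0.563. A further probe of Gart read 0.06, one of Adss 0.03 and one of bur 0.01, and Paics was at 0.02 after quantile normalization.

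Among the 26 gene lists fixed beforehand, 7 passed the camera test in the mean of both ade2 dsRNAs against lhcb dsRNA, 6 lower and 1 higher. Proteasome genes fell by a median of 0.16 on the log2 scale, with 34 of 38 negative (camera adjusted p = 2.43e-06, and adjusted p = 0.653 with an estimated correlation). Of these, Prosbeta7 passed over all genes (-0.55), and 10 genes were lower when adjusted over the list alone. Prosbeta7 was at -0.92 with dsRNA1 and at -0.17 with dsRNA2, a difference past the threshold. Mitochondrial ribosomal protein genes fell by 0.11, with 62 of 70 negative and 0 past the limma threshold singly, either over all genes or adjusted over the list alone. The camera adjusted p was 7.02e-05, and 0.709 with an estimated correlation. Cell cycle and DNA replication genes fell by 0.12, with 23 of 25 negative; 0 passed over all genes in limma and 8 when adjusted over the list alone. The replication genes Mcm3 (-0.23) and PCNA (-0.23) and the mitotic kinase gene Cdk1 (-0.22) are examples from that list. Its adjusted p was 0.000377, and 0.347 with an estimated correlation. The purine synthesis list, with the targeted gene in it, fell by 0.13, and all 10 members were negative, ade2 being the 1 gene past the threshold over all genes and over the list alone (adjusted p = 0.000199, and 0.291 with an estimated correlation). Ribosome biogenesis genes fell by 0.11 (16 of 18 negative; Nop56 at -0.20) and pyrimidine and deoxynucleotide synthesis genes fell by 0.10 (9 of 9 negative). Their adjusted p-values were 0.0145 and 0.042, and 0.653 and 0.555 with an estimated correlation. Over all genes 0 members of either passed in limma, and when adjusted over the list alone 0 of the former and 1 of the latter. Plasmatocyte markers, genes of the macrophage-like blood cell of the fly, rose by a median of 0.12, with 8 of 11 positive (adjusted p = 0.0258, and 0.347 with an estimated correlation). NimC1 rose among them (0.59), and 3 rose when adjusted over the list alone. Under median centring, where the median of all genes was -0.16, the list's median was -0.02 and its call was kept. The Mcm3, PCNA, Cdk1 and Nop56 values were picked after they were seen.

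With an estimated correlation camera called 0 of the 26 lists, and 3 had an unadjusted p under 0.05. With fry, 4 of the 7 passed: purine synthesis (adjusted p = 0.000162), cell cycle, plasmatocyte markers (both 0.0243) and pyrimidine synthesis (0.0399). In the fit blocked by slide, 6 of the 7 passed, all but pyrimidine synthesis. The blocked medians were -0.16 for the proteasome, -0.13 for mitochondrial ribosomal proteins, -0.15 for purine synthesis, -0.15 for the cell cycle, -0.12 for ribosome biogenesis, 0.11 for plasmatocyte markers and -0.09 for pyrimidine synthesis. In the same order the medians were -0.13, -0.11, -0.16, -0.18, -0.03, 0.09 and -0.08 within slide 1, and -0.17, -0.13, -0.14, -0.11, -0.13, 0.17 and -0.11 within slide 2. Without lhcb dsRNA replicate a, 3 of the 7 passed, and without lhcb dsRNA replicate c, 5 did.

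Tested with each dsRNA singly, plasmatocyte markers passed with dsRNA2 (median 0.15, camera adjusted p = 0.00399, and 0.287 with an estimated correlation) and not with dsRNA1 (0.04, adjusted p = 0.197). Pyrimidine synthesis passed with dsRNA1 (-0.11, adjusted p = 0.0284, and 0.594 with an estimated correlation) and not with dsRNA2 (-0.07, adjusted p = 0.113). Neither list differed between the dsRNAs past the threshold (adjusted p = 0.138 and 0.598). The other 5 lists passed with each dsRNA, and with an estimated correlation their adjusted p-values were 0.238 to 0.629 with dsRNA1 and 0.287 to 0.836 with dsRNA2. Single arrays moved some medians by over 1.5 times. For mitochondrial ribosomal proteins the median was -0.06 without lhcb dsRNA replicate a and -0.19 without replicate c. For the cell cycle it was -0.08 without lhcb dsRNA replicate b, and for plasmatocyte markers 0.04 without ade2 dsRNA2 replicate a and 0.06 without lhcb dsRNA replicate b. Over the scalings the medians ranged from -0.29 to -0.08 for the proteasome, -0.24 to -0.06 for mitochondrial ribosomal proteins, -0.27 to -0.09 for purine synthesis and -0.26 to -0.06 for the cell cycle. They ranged from -0.25 to -0.03 for ribosome biogenesis, -0.23 to -0.07 for pyrimidine synthesis and -0.02 to 0.13 for plasmatocyte markers.

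The other 19 lists did not pass, with camera adjusted p-values of 0.0564 to 0.806. Among metabolic lists the median was -0.06 for purine salvage and breakdown, where veil fell (-0.61). That fall came with dsRNA1 (-1.16) and not with dsRNA2 (-0.06). The median was -0.09 for folate and serine metabolism, where pug, methylenetetrahydrofolate dehydrogenase, fell (-0.33). It was -0.10 for the pentose phosphate pathway and 0.03 for glycolysis, where Ldh rose (0.41). When adjusted over the list alone, salvage had 3 lower genes and 1 higher. For cytosolic ribosomal proteins the median was -0.02, and the list passed in opposite directions on the slides, at 0.11 within slide 1 (adjusted p = 6.44e-05) and -0.07 within slide 2 (adjusted p = 0.0488), so slides of a few arrays gave a call either way. It also passed at 0.09 without lhcb dsRNA replicate a and at -0.08 without replicate b, and its adjusted p ran from 1.62e-06 to 0.976 over the alternatives. RpL13 fell (-0.40), while its other probe read 0.32. The median was -0.03 for aminoacyl-tRNA synthetases, where the mitochondrial alanyl-tRNA synthetase gene AlaRS-m fell (-0.28). It was -0.08 for the vacuolar ATPase, where the subunit gene Vha55 fell (-0.39) and the mean of the list was 0.01. Vha55 was at -0.69 with dsRNA1 and at -0.09 with dsRNA2, a difference past the threshold. Stress lists had medians of 0.07 for the integrated stress response (2 genes higher when adjusted over the list alone), -0.05 for the unfolded protein response, 0.01 for heat shock proteins, where Hsp22 rose (0.40), 0.03 for oxidative stress and 0.03 for p53 and DNA damage. The medians of glycolysis, integrated stress, heat shock, oxidative stress and p53 turned negative under median centring, where the median of all genes was -0.16. Some negative medians turned positive under other scalings. With normexp and the 75th percentile, innate immunity was at 0.15 and neuron and muscle markers at 0.12. Autophagy and TOR was at 0.03 with normexp and quantile normalization, and aminoacyl-tRNA synthetases at 0.01 with quantile normalization. Apoptosis was at -0.03 with a mean of 0.02, and innate immunity at -0.02 with a mean of 0.04, where PGRP-SD rose (0.48). JAK-STAT and JNK targets were at -0.07, autophagy and TOR at -0.04 with a mean of 0.01, RNA interference machinery at -0.08, the ecdysone response at 0.14, and neuron and muscle markers at -0.06. The lamellocyte and crystal cell markers had 4 tested genes, too few for the test: PPO3 was at -0.08, PPO2 at -0.07, peb at -0.07 and ItgaPS4 at 0.10, none past the threshold.

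**Figure D3:**
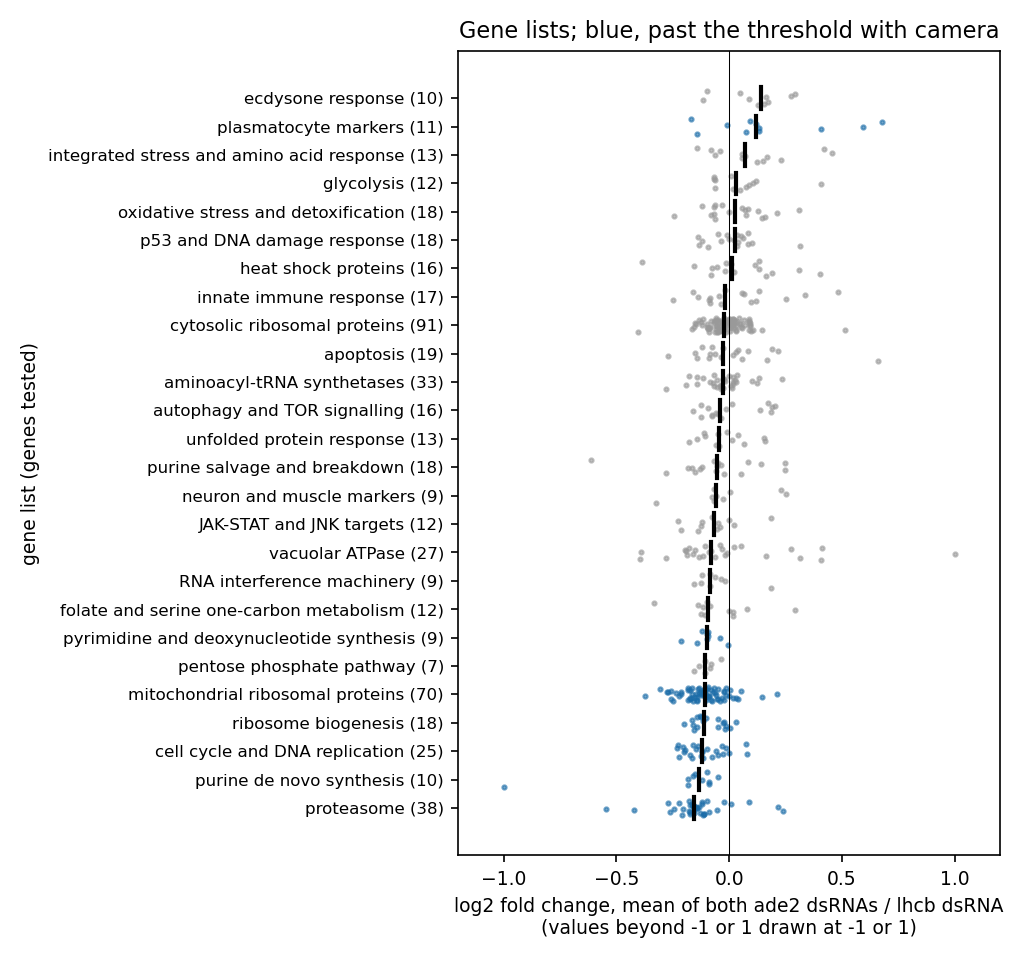
Log2 fold change of each list's genes (mean of both ade2 dsRNAs against lhcb dsRNA); points are genes, black bars medians, blue lists passed the camera test, and values beyond -1 or 1 are drawn at -1 or 1. The proteasome median lies at -0.16 and the plasmatocyte marker median at 0.12. The latter turned to -0.02 under median centring, where the median of all genes was -0.16.

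Between ade2 dsRNA1 and ade2 dsRNA2, 22 genes differed, 11 higher and 11 lower with dsRNA1. The largest differences were in Or85b, 8.86-fold higher with dsRNA1 (log2 3.15, SE 0.31, adjusted p = 0.0189), and sesB, 3.98-fold lower with dsRNA1 (log2 -1.99, SE 0.14, adjusted p = 0.00688). Arc42 was 2.61-fold higher with dsRNA1 (log2 1.39, SE 0.10, adjusted p = 0.00802), having fallen with dsRNA2. Cpr47Eg (0.76), CG11275 (0.71) and CG3168 (0.63) were higher with dsRNA1; the accession-only probe described as CG3168 differed by 0.24, which did not pass (adjusted p = 0.977). Lower with dsRNA1 were veil (-1.10), CG33641 (-0.83), Prosbeta7 (-0.75) and Vha55 (-0.60). None of the 22 was among the 28 shared genes; 6 differed at least 2-fold, and 841 genes had an unadjusted p under 0.05.

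Blocked by slide, 16 genes differed, 15 of them among the 22 and all 10 named ones. The blocked difference was 3.19 for Or85b (3.13 within slide 1, 3.31 within slide 2), 1.38 for Arc42 (1.43 and 1.29), -1.98 for sesB (-1.90 and -2.10) and -0.82 for CG33641 (-0.84 and -0.79). On 1 slide alone limma called 0 genes. The 3 probes of sesB read -1.05 to -0.87 in the mean of both dsRNAs, and the 5 of Vha55 read -0.39 to -0.05. The count was 2 without ade2 dsRNA2 replicate a, 3 or 4 without any 1 ade2 dsRNA1 array, and 14 and 11 without lhcb dsRNA replicates a and b.

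**Figure D4:**
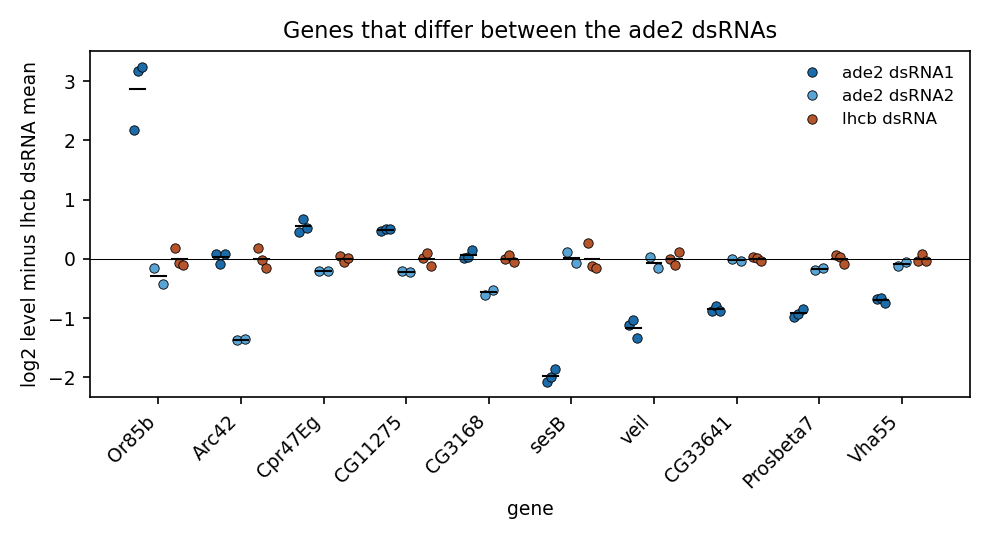
Log2 signal relative to the lhcb dsRNA mean on each array for the 10 named genes that differed between the ade2 dsRNAs; points are arrays and horizontal lines group means. For sesB the dsRNA1 arrays average -1.97 and the dsRNA2 arrays 0.02, and for Arc42 they average 0.02 and -1.36.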

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

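The tests of the lhcb dsRNA's own effect, of knockdown depth, of sequence match and of a level shift of the lists were chosen only after the results were seen.

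The 2 ade2 dsRNAs differed in 22 genes by limma's test of the difference itself. Among the 10 named ones, the log2 difference, dsRNA1 minus dsRNA2, was 3.15 for Or85b, 1.39 for Arc42, 0.76 for Cpr47Eg, 0.71 for CG11275, 0.63 for CG3168, -0.60 for Vha55, -0.75 for Prosbeta7, -0.83 for CG33641, -1.10 for veil and -1.99 for sesB. None of the 10 kept its call through the omission of every array in turn. CG33641 kept it in 7 of the 8 omissions and sesB in 6, but Or85b in 2, and veil and CG3168 in 1 each. The log2 SD of Or85b was 0.60 with dsRNA1, against 0.19 with dsRNA2 and 0.16 with lhcb dsRNA. Of the other 12 genes, Ir64a, gdrd and dpr12 had signals at the floor on all arrays but those of dsRNA2, and CG34283 on the dsRNA2 arrays, which leaves their spread at 0 there and their tests uncertain.

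If a different depth of knockdown were the cause, the larger change would come with the same dsRNA in all 22 genes. It came with dsRNA1 in 13 and with dsRNA2 in 9, and leaving out the 4 genes at the floor and counting only differences above 2 SE, in 12 and 5, which argues against depth as the cause of all 22, whichever dsRNA lowered ade2 more. Depth stays open for the 13 that changed more with dsRNA1: they were picked for differing, so their distance from the share of ade2 (0.880) decides nothing, and 4 of the 13 had opposite signs with the dsRNAs, each above 2 SE, but none of the 4 passed with dsRNA2. As for a difference between the slides, 22 of 22 had the same sign on both, but their selection in these same arrays made that likely. With the slide as a block, all 10 named genes still passed, which argues against the slides as the source for those 10. Another candidate explanation is that some transcripts match 1 of the dsRNAs in sequence and were destroyed with the target: in 12 of 22 the larger change was a fall, 7 with dsRNA1 and 5 with dsRNA2, but the dsRNA sequences were not used here, so this stays open, as does a biological difference between the cells.

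The 28 genes changed alike with both dsRNAs may follow from the loss of ade2, but the same controls serve both comparisons. Without lhcb dsRNA replicate c, 28 of 28 still passed in the mean comparison with the same sign, so there the changes did not rest on that array alone. In addition, 28 of 28 had the same sign on both slides. The genes were picked from these same arrays, which made both outcomes likely. The calls with each dsRNA singly were less stable: 11 of the 28 kept both without lhcb dsRNA replicate c, 12 without replicate a and 8 without replicate b. The changes correlated across genes at 0.763, against 0.448 (0.391 to 0.520) in 100 simulations that shared the controls and had no common effect. These simulations gave every array the same spread. Array weights, lower for a wider spread, were 0.36 and 0.30 for lhcb dsRNA replicates a and c and 1.34 to 1.85 for the others. The simulated correlation may therefore be too low, and the excess decides nothing, as it may come from the shared controls. Genes are also not independent replicates. An effect of the lhcb dsRNA itself cannot be told apart, as there is no other control; 0 of 28 differed between the ade2 dsRNAs by limma (841 of all genes at an unadjusted p under 0.05), which either explanation allows.

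The 7 gene lists moved by small amounts, and a shift with signal level may account for part of that, as the median change of genes grouped by signal ran from 0.09 to -0.08. Against random lists of like signal level, 5 of 7 medians lay outside the central 95%, all but ribosome biogenesis and pyrimidine synthesis. At least 6 had been required to argue against the shift. The lists were also picked for their movement, and the random lists treat genes as independent. The shift therefore stays open for all 7. A part played by 1 control array stays open as well: 5 of 7 still passed without lhcb dsRNA replicate c, all but pyrimidine synthesis and plasmatocyte markers, and 3 of 7 without replicate a, which also ended the calls of mitochondrial ribosomal proteins and ribosome biogenesis. All 7 of 7 medians kept their sign on both slides, though the lists were picked from these same arrays. With the slide as a block 6 of 7 lists still passed, which argues against the slides as the source for those 6.

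Other splits of the arrays were tested with fits of 2 groups. For the 5 ade2 dsRNA arrays against 3 lhcb dsRNA arrays, 1 of 56 splits, the real one, gave as many genes (61, against 32 in the highest other split). This argues against chance if the arrays are independent and interchangeable. The labels do not say that they are independent. Arrays of different groups on the same slide also shared deviations (median correlation 0.18, against -0.13 across slides), so chance is not excluded. For ade2 dsRNA1 against lhcb dsRNA, 1 of 10 splits gave as many (84, highest other 22), and 10 splits are too few for a share under 0.05. The highest other split there set the 3 arrays of slide 1 apart; with the slide as a block the real comparison, fitted on all 8 arrays, gave 126 genes.

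Among 5442 probes that carry only an accession, which the comparisons do not use, 32 passed the threshold in the mean of both ade2 dsRNAs, 24 higher and 8 lower. A probe among them described as CG11436 rose by 2.15 on the log2 scale. Those described as CG3168 and Adss did not pass; the CG3168 probe read 0.24 with dsRNA1 and -0.002 with dsRNA2, a difference of 0.24 (adjusted p = 0.977) against 0.63 for the probe used in the comparisons.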

How the results depend on the processing

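Slide 1 alone, slide 2 alone, accession-only probes and the joint omission of lhcb dsRNA replicates a and c were chosen only after the data were seen. Each group of counts below follows the order ade2 dsRNA1, ade2 dsRNA2, mean of both, same direction with both, and between the ade2 dsRNAs, against 189, 43, 136, 28 and 22. The cause was not tested unless one is given.

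The fall of ade2 kept its direction under every alternative run, at -2.43 to -2.32 with any array left out, and its call under all but the single slides. There it was -2.41 (adjusted p = 0.102) on slide 1 and -2.34 (adjusted p = 0.428) on slide 2, against 7.32e-08 to 0.428 over all alternatives; fewer arrays were tested. On slide 1 limma gave 0 for all 5 counts and 6 lists (unadjusted p under 0.05 in 1775, 1618, 1914 and 1061 genes for the 4 contrasts), and on slide 2 it gave 0 and 7 lists (254, 229, 304 and 148).

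Scaling and background moved the counts. Median centring gave 46, 18, 33, 9 and 11, the authors' values, in the order stated, 52, 12, 29, 7 and 6, and normexp with the 75th percentile 59, 4, 35, 3 and 4. Quantile normalization gave 18 in the same direction with both, and normexp with quantile normalization 53 between the dsRNAs. Median centring put the median of all genes at -0.14, -0.18 and -0.16 in the first 3 contrasts. Higher and lower genes were 2 and 2 with dsRNA2 under normexp with the 75th percentile, and 33 and 22 under normexp with quantile normalization. In the same direction with both they were 13 and 5 with quantile normalization, 5 and 4 with median centring, 2 and 1 with normexp and the 75th percentile, and 3 and 4 in the value table. Between the dsRNAs they were 37 and 16 under normexp with quantile normalization and 2 and 4 in the value table.

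Array weights gave 314 and 70 with each dsRNA, 167 between them and 4 lists. Fits on only the groups compared gave 84, 6, 61, 5 and 6; the mean of both there used all 8 arrays as 2 groups, and the other fits fewer arrays. The ordinary linear model gave 14 with dsRNA2, 71, 10 and 2 between, and was not run for the lists. A 2-fold minimum, stricter by construction, gave 13, 11, 10, 6 and 6. With the slide as a block there were 18 with dsRNA2 and 11 in the same direction. The replicate block gave 43, 11, 15, 7 and 0 (limma; 623 between the dsRNAs at an unadjusted p under 0.05), and the replicate block with the slide block 5, 6, 7, 5 and 0 (limma; 526). The correlations did not show that letters pair the samples: of 7 same-letter pairs 1 correlated above 0.1, and that pair shares a slide. Pairing is not excluded, because deviations cancel within each small group and most same-letter pairs lay on different slides. With accession-only probes there were 23 with dsRNA2 and 11 in the same direction. Without lhcb dsRNA replicates a and c there were 48, 9, 16, 7 and 6. With an estimated correlation camera called 0 lists (3 with an unadjusted p under 0.05; 6 with fry).

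With 1 array left out, where a lone dsRNA2 array is assumed to vary like the others, the counts were 66 to 186, 8 to 27, 23 to 148, 5 to 16 and 2 to 24, and the lists 5 to 10. In the same order they were 66, 11, 64, 6 and 4 without dsRNA1 a; 69, 12, 61, 7 and 3 without dsRNA1 b; 73, 17, 75, 11 and 3 without dsRNA1 c; 84, 8, 23, 5 and 2 without dsRNA2 a; and 84, 16, 46, 5 and 15 without dsRNA2 b. Without lhcb a they were 186, 27, 142, 16 and 14, without lhcb b 90, 12, 39, 8 and 11, and without lhcb c 160, 25, 148, 15 and 24. Of 26 genes named for the mean comparison and called in it, 11 kept the call through every omission, ade2, CG11436, Fkbp59 and HtrA2 among them.

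Over all alternatives, values of named genes past the threshold stayed past it 602 times and lost the call 368 times, and lists 155 and 41 times. Values that had not passed stayed so 241 times and reversed 2 times: Paics, at 0.0233 with quantile normalization and at 0.0198 with normexp and quantile normalization. No filter, well-above-background signal on all 8 arrays, the mean of probes, and a trended robust prior left all 5 totals within 1.5 times, but not the directions: with no filter, higher and lower genes were 141 and 82 with dsRNA1 and 102 and 69 in the mean of both, and with the trended robust prior 146 and 59, and 116 and 58. Without lhcb c they were 109 and 51, and 91 and 57. Signals near background limit what can be seen: 9419 of the 10007 genes were well above it on all arrays.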

Other observations

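The enrichment of cytochrome P450 genes, the purine list without ade2 and the list tests in comparisons other than the mean of both were chosen only after the results were seen.

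Cytochrome P450 genes, which encode oxidising enzymes of hormone, lipid and toxin metabolism, stood out among the genes that rose in the mean of both ade2 dsRNAs. Of 57 tested family members 9 rose (15.8%), against 96 of 9950 other genes (0.965%). Fisher's exact two-sided p was 6.45e-09, or 7.74e-08 adjusted over the 12 name families looked at that had tested genes, none of the others passing (0.879 to 1). The 9 were Cyp28d1 (0.66), Cyp4p1 (0.58), Cyp6d5 (0.54), Cyp28a5 (0.50), Cyp6a23 (0.44), Cyp12a4 (0.40), Cyp4d8 (0.35), Cyp4d20 (0.31) and Cyp6a20 (0.24). The family median was 0.14 on the log2 scale, with 45 of 57 positive, at 0.18 with dsRNA1 and 0.13 with dsRNA2. It was 0.10 after quantile normalization. Under median centring, where the median of all genes was -0.16, it was 0.00 and 1 member rose. With the slide as a block 7 rose, without lhcb dsRNA replicate c 6 and with normexp and the 75th percentile 3. The median lay at percentile 100 of random lists of like level. The family was picked after its members were seen to rise, so this does not settle whether a shift with signal level plays a part. Fisher's test and the random lists also treat genes as independent. The camera p with an estimated correlation was 0.000869, not adjusted for that choice. The family's definition was narrowed to leave out cyclophilins after a first percentile had been seen.

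Between the ade2 dsRNAs 4 of the 26 lists passed the camera test. None of their members was among the 22 genes that passed singly in limma. Cytosolic ribosomal protein genes tended lower with dsRNA1 (median -0.11, 75 of 91 negative, camera adjusted p = 1.09e-05, and 0.866 with an estimated correlation). The median turned to 0.01 under quantile normalization and to 0.01 under normexp with quantile normalization. Glycolysis genes tended higher with dsRNA1, with 12 of 12 positive (median 0.15, camera adjusted p = 2.3e-05, and 0.608 with an estimated correlation). Their median was 0.14 with the slide as a block, 0.14 within slide 1, 0.12 within slide 2, where 10 of 12 were positive, and 0.11 to 0.21 over the scalings. Aminoacyl-tRNA synthetases (median 0.07, camera adjusted p = 0.0288, and 0.866 with an estimated correlation) and innate immune genes (0.10, 0.0295 and 0.608) tended higher with dsRNA1. The innate immune median was 0.00 within slide 1 and 0.16 within slide 2, and that of the synthetases 0.03 and 0.07.

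With each dsRNA singly against lhcb dsRNA, 10 lists passed camera with dsRNA1 and 7 with dsRNA2, of which 4 and 1 had not passed in the mean of both. With dsRNA1 these were glycolysis (median 0.11, adjusted p = 0.00564, and 0.623 with an estimated correlation), cytosolic ribosomal proteins (-0.07, 0.0482 and 0.766), the integrated stress response (0.08, 0.0284 and 0.391) and innate immunity (0.02, 0.0284 and 0.535). The medians of glycolysis, integrated stress and innate immunity turned negative under median centring, where the median of all genes was -0.14. That of innate immunity was 0.24 under normexp with the 75th percentile, with 17 of 17 positive against 10 of 17. That of cytosolic ribosomal proteins was positive under quantile normalization and within slide 1. With dsRNA2 it was the ecdysone response (0.20, 0.0364 and 0.349), positive under all scalings. Its median was 0.05 under median centring, where the median of all genes was -0.18. It was 0.08 under normexp with quantile normalization and 0.10 in the authors' values.

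Without ade2, the other 9 genes of purine synthesis had a median of -0.12, all of them negative by the probe used, though Gart, Adss and bur each had a probe above 0 (camera p = 0.00123, and 0.0212 with an estimated correlation). The median lay at percentile 1.47 of random lists of like level, and it was -0.09 after quantile normalization, with 1 gene positive.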
